A study of Mus musculus with 12 samples.

How the data were processed

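RNA was measured in 12 mammary tumours grown in the fourth mammary fat pad of female FVB/N mice from NIC cells, a mouse breast cancer line driven by ErbB2. There were 4 groups of 3 tumours: p66Low parental, p66High parental, p66Low aggressive and p66High aggressive. Per the labels' protocols, total RNA was extracted from bulk tumour, depleted of ribosomal RNA and made into stranded libraries. Per the submitters' processing notes, the authors used Trimmomatic 0.32, STAR 2.3.0e and featureCounts 1.4.4 with the mm10 genome build, and deposited whole-number read counts per gene that are not normalized. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with near-identical copies or overlapping genes are therefore uncertain, such as Gapdh, Eno1, Pgk1, ribosomal protein genes, Saa1 with Saa2, and Ccl21a.

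The deposited count table held 39017 genes by Ensembl identifier, and 37607 of them (96.4%) matched a GENCODE gene of mm10, which gave symbols, biotypes and coordinates. A total of 9307 genes had a count of 0 in every tumour. Total counts ranged from 17.4 to 76.1 M (mega-counts) per tumour. A count of 3, used as the floor for an undetected gene, was worth 0.0394 CPM (counts scaled to a library of 1 M) in the deepest library and 0.156 CPM in the shallowest. Floors and counting intervals (95%) cover counting error only. No pair of tumours within a group agreed within sampling noise: the lowest chi-square per degree of freedom was 21.1. All 12 libraries were kept.

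Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 19370, and scaled by TMM (trimmed mean of M-values). A quasi-likelihood F-test was fitted to all 12 tumours in 4 groups with 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are on the log2 scale. Their standard error (SE) is the absolute log2 fold change over the square root of the F statistic. Levels are CPM with the standard deviation (SD, n = 3) over TMM-scaled libraries. The comparisons were p66High against p66Low within parental and within aggressive tumours, aggressive against parental within p66Low and within p66High, the interaction of both factors, and each factor averaged over the other.

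A total of 52 gene lists covering pathways and cell types were fixed before the data were examined, and 51 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2. Camera was repeated with an estimated correlation, and fry was run as a second test. Adjusted p-values of lists are over the 51 lists. The groups, the tests, the main alternatives and the rule for naming genes were also fixed before the data were examined. The rule named Shc1 and Erbb2 in every tumour. For each comparison it named the 8 highest and 8 lowest protein-coding genes past the threshold whose tumours did not overlap between groups and whose mean reached 2 CPM in the higher group. It also named up to 4 members of each called list with the smallest p, the 5 highest and 5 lowest genes of the interaction, and the 5 genes of each direction pair that changed most in both of 2 parallel comparisons. Outside the rule, genes chosen after their values were seen were Slc2a1, Vegfa, Adipoq, Sod2 and Cat in p66High against p66Low parental tumours, Vegfa and Mki67 in p66High selection and Mdm2 in p66High against p66Low aggressive tumours. In p66Low selection they were Cdkn1a, Phlda3, Aen, Mdm2, Sesn1, Trp53, Epcam, Myc, Cxcl9, Cxcl10 and Cd274. Others are marked where they appear. Some genes that the rule took are not reported here.

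Alternatives were other scalings, DESeq2 1.42.0, limma-voom, a robust fit, other filters, a minimum log2 fold change of 1, fits of only the 6 tumours compared, summing of tumours of 1 group whose titles share a number, and leaving out each tumour in turn. Chosen after seeing the data were fits without the 3 libraries rich in lymph node genes (more than 20 summed CPM), a lymph node covariate, and counts without chromosomes 1 and 15. The fit was tested on simulated counts with 200 genes changed by known folds. The p66High against p66Low parental simulation (19027 genes) also shifted chromosome 1 by 0.5 log2, and that of p66Low selection p53 targets by -1. The former recovered 25.4%, 67.2% and 97.0% of genes changed 1.5-, 2- and 4-fold. The interaction (19042 genes), without such shifts and so not comparable, recovered 1.49%, 28.4% and 74.2%. Titles of p66High parental replicates 1 and 2 share a number, as do those of p66High aggressive replicates 1 and 2. The labels do not say what the number means or whether tumours of a group came from separate mice, so p-values measure the spread between these samples.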

Results

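Gene expression was measured in 12 bulk mammary tumours formed by NIC cells, which are ErbB2-positive and lack p66ShcA, the longest protein isoform of the Shc1 adaptor gene. The p66High cells constitutively overexpressed p66ShcA and the p66Low cells did not. Each line was used as parental cells and as an aggressive population that had been selected by serial growth in the fat pad and re-explanted, which the submitters describe as faster growing and more metastatic. There were 3 tumours in each of the 4 groups. Total counts in mega-counts (M) were 38.6, 25.8 and 38.7 M for p66Low parental, 43.5, 29.4 and 76.1 M for p66High parental, 17.4, 61.2 and 71.8 M for p66Low aggressive, and 38.4, 25.3 and 24.7 M for p66High aggressive tumours.

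Shc1 (ENSMUSG00000042626, mm10 chromosome 3, 89418443 to 89430027) followed the labels in every tumour. Its level was 65.0, 59.0 and 69.4 CPM in p66Low parental and 60.9, 65.3 and 69.9 CPM in p66Low aggressive tumours. It was 271, 234 and 223 CPM in p66High parental tumours, and 236, 246 and 774 CPM in p66High aggressive tumours. The log2 difference between p66High and p66Low was 1.91 (SE 0.37, edgeR adjusted p = 0.0088) in parental and 2.68 (SE 0.38, adjusted p = 0.000941) in aggressive tumours, and the latter was 1.86 without p66High aggressive replicate 3. Counts per gene do not separate the p66 isoform from the other Shc1 isoforms. Mouse Erbb2 (ENSMUSG00000062312, chromosome 11, 98412470 to 98437716) lay between 50.6 and 89.6 CPM in the 12 tumours. It passed in no comparison, with log2 differences of -0.02, -0.15, 0.06 and 0.19 in the order described. Whether its reads are from the driving ErbB2 was not tested.

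Libraries differed in the level of marker genes of other tissues. The summed level of 10 lymph node stroma markers was 72.9 CPM in p66High parental replicate 3, 210 CPM in p66Low aggressive replicate 1 and 307 CPM in p66Low aggressive replicate 2, against 0.550 to 4.08 CPM in the other 9 tumours. The same 3 libraries led in B cell genes, whose summed level, without plasma cell and immunoglobulin genes and without Cr2 and Fcer2a, which are also in the stroma list, was 34.7, 121 and 170 CPM in them and 2.97 CPM in p66Low aggressive replicate 3. The summed level of 15 adipocyte markers ranged from 54.4 CPM in p66High aggressive replicate 3 to 593 CPM in p66High parental replicate 1.

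**Figure D1:**
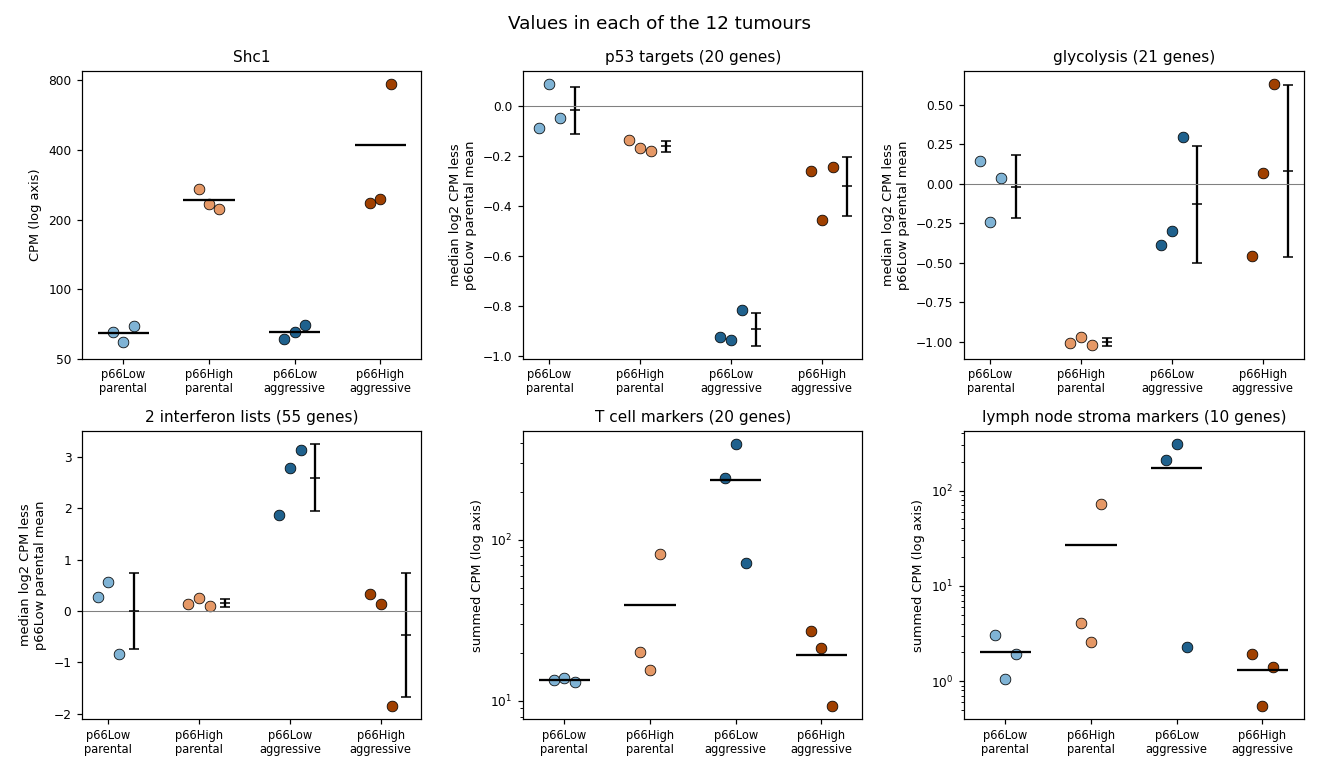
Each point is 1 of 12 tumours, grouped by cell line, with CPM on log axes for Shc1 and 2 summed marker lists and the median log2 CPM of a list less the p66Low parental mean for the others. Horizontal bars are means, error bars are SD (n = 3), and the 3 p66Low aggressive tumours lie between -0.93 and -0.82 for p53 targets.

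The first comparison addressed how tumours of unselected p66High and p66Low cells differed. Tumours of p66High parental cells expressed less of several glycolysis and hypoxia genes than tumours of p66Low parental cells. Ldha, which makes lactate from pyruvate, was at 691 ± 36.1 CPM against 1774 ± 325 CPM (SD, n = 3), and Car9, a carbonic anhydrase induced by low oxygen, at 7.36 ± 0.42 CPM against 53.5 ± 13.3 CPM. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.70 on the log2 scale (adjusted p = 0.00758). The chemokine gene Cxcl1 rose by 2.13. Genes of chromosome 1 were higher as a block.

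Of 19370 genes tested, 1565 (8.08%) passed, with 770 higher and 795 lower in p66High tumours, and 614 of them changed at least 2-fold. All 3 tumours of one group lay above all 3 of the other for 1560 of these genes. The same held for 5804 of the 19370 genes tested, where chance gives 10%. The highest fold changes were of Brinp3 (log2 7.18, SE 0.43, adjusted p = 2.26e-05, 112 ± 18.6 CPM against 0.831 CPM), the RNA-binding protein gene Igf2bp2 (6.06), the transcription factor gene Sox14 (5.04) and Bspry (4.94). They were followed by the magnesium channel gene Trpm6 (4.40), the secreted Wnt inhibitor gene Wif1 (4.35), Htra4 (4.05) and Fermt1 (4.04). Among the lowest were Zfp385b (-6.79), Zfp612 (-5.94), the incretin receptor gene Gipr (-5.20) and Cntnap2 (-5.10), then Tmem35 (-4.92), Ranbp17 (-4.53) and Shisa7 (-4.52). Ranbp17 lies beside the homeobox gene Tlx3 on chromosome 11, and Tlx3 was at least 92.7-fold lower, with no count in the p66High parental tumours (floor of 3 counts over the group). Erbb4, a receptor of the ErbB family, fell by 4.38. Gipr did not pass without any 1 of the 6 tumours except p66Low parental replicate 2 (adjusted p = 0.0539 to 0.0929).

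Camera called 14 lists, 11 higher and 3 lower. All 9 of the 21 glycolysis genes that passed were lower (19 when adjusted over the list alone), with a median log2 change of -0.94 and a camera adjusted p of 1.87e-09. They included Ldha (-1.36), Eno1 (-1.88), the hexokinase gene Hk1 (-0.93) and the phosphofructokinase gene Pfkl (-0.87). The glucose transporter gene Slc2a1 had a log2 change of -1.28 that did not pass (adjusted p = 0.0665). Of 20 hypoxia response genes, 3 were lower and none higher (12 lower and 1 higher when adjusted over the list alone), with a median of -0.95 and an adjusted p of 0.000192: Car9 (-2.86), Car12 (-0.90) and the adenylate kinase gene Ak4 (-1.34). Vegfa, the main angiogenic factor, was at 88.1 CPM against 296 CPM and did not pass (adjusted p = 0.0971). The cholesterol synthesis list was lower (median -0.31, adjusted p = 0.00727), with its transcription factor Srebf2 at -0.69 among the 2 of 23 members past the test (3 when adjusted over the list alone). Each of these 3 lists had an adjusted p = 0.806 with an estimated correlation.

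Among the lists called higher, that of nuclear-encoded oxidative phosphorylation had 5 of 30 members past the test (5 higher and 1 lower when adjusted over the list alone), with a median of 0.09 and an adjusted p of 0.0344. Of these, Sdhc (0.54) and Ndufs1 (0.67) lie on chromosome 1 and Atp5a1 (0.61) on chromosome 18. NF-kB and inflammatory cytokine genes had 3 of 22 past the test (5 when adjusted over the list alone; median 0.14, adjusted p = 0.0453), namely Cxcl1, the alarmin gene Il33 (1.21) and Cxcl5 (1.41). YAP and TEAD targets had 2 of 18 past the test (4 when adjusted over the list alone; median 0.22, adjusted p = 0.0242), namely Nuak2 (0.69) and Amotl1 (0.38). The unfolded protein response list was called with Dnajc3 (0.59) as its 1 of 16 members past the test (1 when adjusted over the list alone; median 0.19, adjusted p = 0.0462). With an estimated correlation each of these 4 lists had an adjusted p = 0.806.

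Markers of other cell types were called higher as lists while few or no members passed alone, and each of these 7 lists had an adjusted p = 0.806 with an estimated correlation. Adipocyte markers had a median of 2.02 (adjusted p = 0.00207) and endothelial markers of 0.52 (adjusted p = 0.00683). Fibroblast markers had a median of 0.65 (adjusted p = 0.0292), collagen and matrix genes of 0.44 (adjusted p = 0.0344) and mast cell markers of 1.60 (adjusted p = 0.0344). No member of these 5 lists passed in edgeR, over all genes or when adjusted over the list alone, while 5 of 15, 5 of 18, 2 of 18, 8 of 26 and 2 of 7 had an unadjusted p under 0.05. The fat cell hormone gene Adipoq was at 20.8 ± 10.99 CPM against 4.26 ± 5.38 CPM (adjusted p = 0.31). NK and cytotoxic markers (median 1.83, adjusted p = 0.00683) had 2 of 12 past the test (2 when adjusted over the list alone), the receptor gene Ncr1 (3.13) and the granzyme gene Gzma (2.14). The T cell list had a median of 2.73 (adjusted p = 0.00783), 12 of 20 members with an unadjusted p under 0.05 and none past the threshold over all genes or when adjusted over the list alone, and a median of 0.53 (adjusted p = 0.372) without p66High parental replicate 3, the library with lymph node genes. Lists of p53 targets (median -0.18), ErbB2 and Shc signalling (0.08) and antioxidant enzymes other than NRF2 targets were not called. The superoxide dismutase gene Sod2 (0.11, adjusted p = 0.576) and the catalase gene Cat (-0.17, adjusted p = 0.253) did not pass.

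On chromosome 1, 346 of 1133 tested genes passed, 329 of them higher, against 5.88% of genes on chromosomes other than 1 and 15. The median log2 change of its expressed coding genes was 0.48. On chromosome 15, 188 of 714 tested genes passed, 180 of them lower, with a median of -0.43, and its median relative to all 12 tumours was 0.37, 0.06 and 0.29 in p66Low parental and -0.16, -0.18 and -0.12 in p66High parental tumours. Without both chromosomes 846 genes passed. None of the 14 called lists was called by camera with an estimated correlation (adjusted p = 0.806 for each, 0 of 51 lists with an unadjusted p under 0.05) or by fry, which had 8 lists with an unadjusted p under 0.05.

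The count fell to 889 without p66Low parental replicate 1, 871 without p66Low parental replicate 3, 892 without p66High parental replicate 1, 960 without p66High parental replicate 3, the library with lymph node genes, and 838 without all 3 libraries rich in these genes, 2 of them p66Low aggressive. It was 908 when tumours whose titles share a number were summed and 2549 with DESeq2. List calls that ended without 1 tumour were those of oxidative phosphorylation (adjusted p = 0.514 without p66Low parental replicate 2, 0.257 without p66High parental replicate 2) and of cholesterol synthesis (0.188), collagens (0.122), YAP targets (0.0985) and inflammatory genes (0.0784) without p66Low parental replicate 1. Without p66Low parental replicate 2 those of fibroblasts (0.125), the unfolded protein response (0.202), collagens (0.0833) and mast cells (0.0705) ended. Calls also ended of inflammatory genes (0.0672) and the unfolded protein response (0.0511) without p66Low parental replicate 3, and of these same lists without p66High parental replicate 1 (collagens 0.104, YAP 0.0646, unfolded protein 0.0605, fibroblasts and inflammatory 0.0554), replicate 2 (collagens 0.0729, fibroblasts 0.0674, unfolded protein 0.0513) or replicate 3 (inflammatory 0.0931). The median of oxidative phosphorylation was 0.17 and -0.01 without p66Low parental replicate 1 and 2 and 0.15, -0.01 and 0.13 without p66High parental replicate 1, 2 and 3, and that of cholesterol synthesis was -0.19, -0.50 and -0.21 without p66Low parental replicate 1, 2 and 3. Medians were 0.31 for inflammatory genes without p66Low parental replicate 2, 1.13 for NK markers without p66High parental replicate 3, 2.49 for mast cells without p66Low parental replicate 3 and 3.21 for adipocytes without p66Low parental replicate 1. Of the list members named, Car12, Ak4, Srebf2, Il33, Cxcl5, Nuak2, Amotl1, Ncr1 and Gzma did not pass in some of the 6 fits without 1 tumour (adjusted p up to 0.152).

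The second comparison addressed in vivo selection of p66Low cells. Tumours of p66Low aggressive cells carried far more expression of interferon response, antigen presentation and T and NK cell genes than p66Low parental tumours, and less expression of p53 target genes. B2m, the light chain of class I antigen-presenting molecules, was at 1489 ± 711 CPM against 124 CPM. Ciita, the activator of class II antigen presentation, was at 68.4 ± 5.22 CPM against 7.71 CPM, and Cd8a, a marker of cytotoxic T cells, at 16.4 CPM against 0.420 CPM. Cdkn1a, the p53 target that encodes p21, was at 4.02 ± 1.20 CPM against 42.5 ± 11.8 CPM. Replicates 1 and 2 of the p66Low aggressive group held the lymph node genes.

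A total of 3221 genes (16.6%) passed the same test, 1860 higher and 1361 lower, and 1723 of them changed at least 2-fold. With scaling by library size alone, 73.6% of the called genes were higher, against 57.7% in the main analysis. Groups did not overlap for 3103 called genes and for 32.9% of genes tested, where chance gives 10%. Several of the highest genes belong to B cells or lymph node stroma: the chemokine gene Ccl21a was at least 255-fold higher, and the counting interval of the ratio was 301 to 8993 for Ms4a1 and 59.0 to 1769 for Fcrla. Folr4 was at least 79.0-fold higher and Dmbt1 at least 116-fold. The bounds of Ccl21a, Folr4 and Dmbt1 were 59.8, 35.2 and 10.47 without p66Low aggressive replicate 2, and 467, 125 and 205 without replicate 3. These 3 and Ms4a1 did not pass without p66Low aggressive replicate 2 or without p66Low parental replicate 1 or 3 (adjusted p = 0.0511 to 0.116). Nor did Ccl21a, Dmbt1 and Ms4a1 without p66Low parental replicate 2 (0.0533 to 0.0832) or Ccl21a without p66Low aggressive replicate 1 (0.0780). The transcription factor genes Sox11 (log2 7.48, 42.6 ± 22.1 CPM against 0.225 CPM, adjusted p = 4.18e-05) and Sox2 (counting interval of the ratio 86.5 to 2590) also rose. The lowest were Dppa1 (-5.85), Clic3 (-5.69), Tmem35 (-5.58), the retinol-binding protein gene Rbp7 (-4.52, 5.81 ± 1.57 CPM against 131 ± 55.1 CPM), Scml2 (-4.34), the sodium channel gene Scnn1b (-4.02), the collagen gene Col10a1 (-4.02) and Eda2r (-3.56).

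All 27 genes of interferon gamma response and antigen presentation were higher (27 when adjusted over the list alone), with a median log2 change of 3.58, a camera adjusted p of 1.27e-19 and an adjusted p = 0.50 with an estimated correlation. They included Ciita (3.15), the transcription factor gene Irf1 (1.84), the peptide transporter gene Tap2 (1.95) and B2m (3.58). Of 28 type I interferon response genes, 20 were higher (28 when adjusted over the list alone), with a median of 2.19 and an adjusted p of 9.18e-11, which was an adjusted p = 0.571 with an estimated correlation. The signal transducer Stat2 (1.70) and the antiviral genes Oas3 (3.50) and Oas2 (3.12) were among them. The median of both lists together, relative to the p66Low parental mean, was 1.87, 2.79 and 3.14 in the 3 p66Low aggressive tumours, and the highest of these was replicate 3, which had 2.28 CPM of lymph node stroma markers. Of 22 NF-kB and inflammatory genes, 15 were higher (17 when adjusted over the list alone; median 1.13, adjusted p = 1.26e-10), and this call held with an estimated correlation (adjusted p = 0.0318). Birc3 (1.35), Icam1 (2.56), Relb (1.06) and Cxcl5 (2.94) were among them. The interferon-induced chemokine genes Cxcl9 (5.59) and Cxcl10 (3.57), and Cd274 (3.25), which encodes PD-L1, were chosen after their values were seen.

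Of 20 T cell markers, 19 were higher (20 when adjusted over the list alone), with a median of 5.55 and an adjusted p of 4.31e-12, against an adjusted p = 0.564 with an estimated correlation. Icos rose by 6.75, Cd28 by 5.49, Cd8a by 5.37 and Cd3g by 5.33. Their summed level was 241 and 394 CPM in the libraries with lymph node genes, 72.0 CPM in p66Low aggressive replicate 3 and 13.2 to 13.9 CPM in p66Low parental tumours. NK and cytotoxic markers had 11 of 12 higher (12 when adjusted over the list alone; median 3.88, adjusted p = 6.49e-09, adjusted p = 0.50 with an estimated correlation), with Ncr1 at 4.66 and Nkg7 at 5.26. Dendritic cell markers had 14 of 17 higher (15 when adjusted over the list alone; median 2.72, adjusted p = 1.68e-08, adjusted p = 0.554 with an estimated correlation), with the integrin genes Itgae at 2.46 and Itgax at 1.58. Macrophage markers had 9 of 20 higher (10 when adjusted over the list alone; median 0.60, adjusted p = 0.000331, adjusted p = 0.571 with an estimated correlation), including Aif1 (1.25) and C1qc (0.97). Neutrophil markers had 4 of 11 higher (6 when adjusted over the list alone; median 1.24, adjusted p = 0.0111, adjusted p = 0.50 with an estimated correlation), including Csf3r (1.93) and S100a9 (2.96). S100a9 was at 1.69 without p66Low aggressive replicate 2 (adjusted p = 0.153), and did not pass without p66Low parental replicate 2 (0.0530) or 3 (0.0881) either.

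B and plasma cell markers had 11 of 16 higher and 1 lower (14 and 1 when adjusted over the list alone), with a median of 7.27, or 7.14 with undetected genes at their bound, and an adjusted p of 5.46e-05 (adjusted p = 0.571 with an estimated correlation). The plasma cell gene Igj rose by 6.61, and Sdc1, which epithelial cells also express, fell by 0.63. Lymph node stroma markers had 4 of 10 higher (9 when adjusted over the list alone), with a median of 8.18, or 6.81 at the bound, and an adjusted p of 0.00102 (adjusted p = 0.685 with an estimated correlation), including Enpp2 (5.11) and the follicle chemokine gene Cxcl13 (5.98). Both did not pass without any 1 p66Low parental tumour or without p66Low aggressive replicate 2 (adjusted p = 0.0544 to 0.132), nor did Cxcl13 without p66Low aggressive replicate 1 (0.0755). Without the 3 libraries rich in lymph node genes, which leaves p66Low aggressive replicate 3 as the 1 tumour of its group, 705 genes passed. In that fit 25 interferon gamma genes (median 4.10), 8 type I interferon genes (2.77), 9 T cell markers (3.54) and 4 NK markers (3.44) were still higher, and the B cell list was not called (median 1.41, adjusted p = 0.0822).

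Of 20 p53 target genes, 15 were lower (17 when adjusted over the list alone), with a median of -0.90 and an adjusted p of 7.61e-12, and the call held with an estimated correlation (adjusted p = 0.0318). Ccng1 was at 91.3 ± 4.26 CPM against 219 ± 4.68 CPM (log2 -1.26, adjusted p = 2.22e-05). Eda2r (-3.56), the death effector gene Bax (-1.18), Zmat3 (-2.02), Phlda3 (-2.48), Aen (-1.14) and Mdm2 (-0.53), the p53 ubiquitin ligase, were lower with Cdkn1a (-3.38). Sesn1 had a log2 change of 0.34 (adjusted p = 0.193) and the p53 gene Trp53 itself of -0.40 (adjusted p = 0.276). The median over the list lay at -0.92, -0.93 and -0.82 in the 3 tumours, relative to the p66Low parental mean. Without the libraries rich in lymph node genes the list was still called, with a median of -0.83. The list of epithelial adhesion and identity had 3 higher and 3 lower of 24 members and a median of 0.01, with Epcam at 0.02.

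Camera called 20 lists, 14 higher and 6 lower. Cytosolic ribosomal protein genes had 18 of 26 lower (24 when adjusted over the list alone), with a median of -0.48, an adjusted p of 3.56e-10 and an adjusted p = 0.571 with an estimated correlation. Rpl3 (-0.93) and Rps18 (-0.64) were among them. MYC targets had 3 of 21 lower (4 when adjusted over the list alone; median -0.27, adjusted p = 0.014, adjusted p = 0.899 with an estimated correlation), namely Nop16 (-0.59), nucleolin (Ncl, -0.69) and Pes1 (-0.31), while Myc itself was at -0.10 (adjusted p = 0.865). Fatty acid oxidation had 4 of 19 lower (7 when adjusted over the list alone; median -0.26, adjusted p = 0.014, adjusted p = 0.571 with an estimated correlation), with Acadl at -0.74 and Decr1 at -0.47. Oxidative phosphorylation had 4 of 30 lower (4 when adjusted over the list alone; median -0.15, adjusted p = 0.0272, adjusted p = 0.899 with an estimated correlation), including Sdha (-0.36) and Uqcrfs1 (-0.37). Heat shock genes had 3 of 13 lower (3 when adjusted over the list alone; median -0.25, adjusted p = 0.0221, adjusted p = 0.571 with an estimated correlation), with Hspb1 at -1.34. YAP and TEAD targets had 5 of 18 higher (7 higher and 1 lower when adjusted over the list alone; median 0.39, adjusted p = 0.0073, adjusted p = 0.565 with an estimated correlation), led by Ankrd1 (2.52) and Crim1 (1.29). Mesenchymal genes had 5 of 24 higher and 1 lower (5 and 1 when adjusted over the list alone; median 0.68, adjusted p = 0.0212, adjusted p = 0.729 with an estimated correlation), including Tgfbi (1.82), Zeb2 (1.17) and Vim (0.83). Fibroblast markers (median 0.90, adjusted p = 0.0266, adjusted p = 0.899 with an estimated correlation) had the complement gene C3 (2.96) among 2 of 18 members past the test (1 when adjusted over the list alone). The mast cell list was called on a median of 3.06 (adjusted p = 0.0142, adjusted p = 0.571 with an estimated correlation) with Hdc (2.82) as its 1 of 7 members past the test (6 when adjusted over the list alone).

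The count was 2034 without p66Low parental replicate 1, 1545 without p66Low parental replicate 3, 1547 without p66Low aggressive replicate 2 and 2126 when only the 6 tumours were fitted, and without the libraries rich in lymph node genes the medians of the mesenchymal and fibroblast lists were -0.04 and -0.46. List calls that ended without 1 tumour were those of oxidative phosphorylation (adjusted p = 0.522), mesenchymal genes (0.106), fibroblasts (0.0668), MYC targets (0.0632), fatty acid oxidation and YAP targets (0.0575 each) without p66Low parental replicate 1. Calls also ended of fibroblasts (0.152) without replicate 2 and of MYC targets (0.171) and heat shock genes (0.0790) without replicate 3 of that group. Those of fibroblasts (0.158), mesenchymal genes (0.103), mast cells (0.0574) and oxidative phosphorylation (0.0536) ended without p66Low aggressive replicate 1. So did those of fibroblasts (0.454), mesenchymal genes (0.117), fatty acid oxidation and oxidative phosphorylation (0.103 each) and mast cells (0.0749) without replicate 2, and of MYC targets (0.162) and heat shock genes (0.0600) without replicate 3. Medians were -0.07 for oxidative phosphorylation without p66Low parental replicate 1, -0.10 for MYC targets and -0.14 for heat shock genes without p66Low parental replicate 3, 0.45 for mesenchymal genes without p66Low aggressive replicate 1, and 0.39, 0.24 and 0.25 for mesenchymal genes, YAP targets and fibroblasts without p66Low aggressive replicate 2. Of the other list members named, Csf3r, Ncl, Pes1, Decr1, Uqcrfs1, Vim, C3 and Hdc did not pass in some of the 6 fits without 1 tumour (adjusted p up to 0.194).

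**Figure D2:**
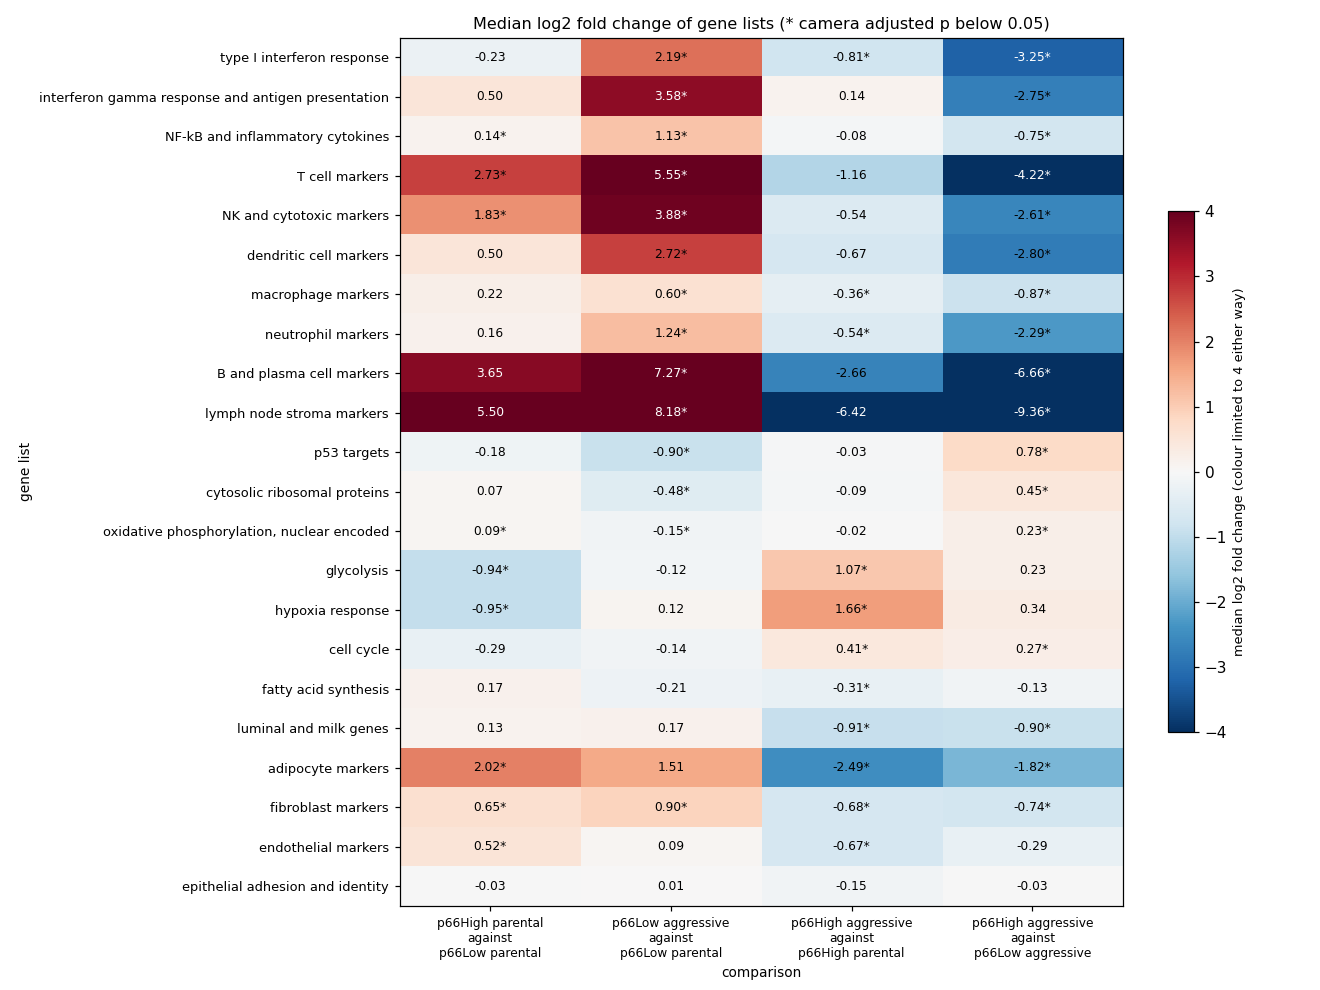
Each cell gives the median log2 fold change of 1 of 22 gene lists (vertical axis) in 1 of 4 comparisons (horizontal axis), coloured up to 4 either way, and an asterisk marks a camera adjusted p below 0.05. Interferon lists had medians of 2.19 and 3.58 in p66Low aggressive against p66Low parental tumours and of -3.25 and -2.75 in p66High aggressive against p66Low aggressive tumours.

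The third comparison addressed the same selection of p66High cells. Tumours of p66High aggressive cells expressed more glycolysis and hypoxia genes than p66High parental tumours, and less of several milk protein, adipocyte and fatty acid synthesis genes. Pfkp, a phosphofructokinase, was at 539 ± 112 CPM against 231 ± 31.9 CPM, and Car9 at 58.5 ± 36.9 CPM against 7.36 ± 0.42 CPM (SD, n = 3). Vegfa was at 156, 382 and 1135 CPM in the 3 tumours against a mean of 88.1 CPM (log2 2.66, adjusted p = 0.0262). Without p66High aggressive replicate 3 that change was 1.60 and did not pass (adjusted p = 0.0810), nor did it without any 1 p66High parental tumour (0.0846 to 0.114). The milk protein gene Csn2 was at 0.172 CPM against 22.5 CPM.

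A total of 1150 genes (5.94%) passed, 603 higher and 547 lower, and 642 of them changed at least 2-fold. Groups did not overlap for 1148 called genes and for 32.6% of genes tested, where chance gives 10%. The highest fold changes were of Gipr (4.97), the homeobox gene Hoxa10 (4.79, 29.9 ± 0.582 CPM against 1.09 ± 0.0961 CPM, adjusted p = 1.55e-05), Dlgap1 (4.48) and the cartilage collagen gene Col2a1 (4.18, with 497 CPM in p66High aggressive replicate 3). The cation channel gene Trpm3 (3.91), Zfp641 (3.73), Chst9 (3.55) and the polarity gene Celsr1 (3.41) came next. The lowest were of Csn2 (-6.95), the acute phase genes Saa1 (-6.60) and Saa2 (-6.41), Sptlc3 (-6.56, counting interval of the ratio 26.5 to 799), Clic6 (-5.50), the adipocyte hormone gene Retn (-5.04), the surfactant protein gene Sftpd (-4.15) and Aldh1a7 (-3.91). Without p66High aggressive replicate 3, Gipr was at 2.75 (adjusted p = 0.130) and Col2a1 at 2.12 (adjusted p = 0.129), and neither passed without any 1 p66High parental tumour (0.0912 to 0.136). Retn did not pass without any 1 of the 6 tumours (0.0680 to 0.154). Aldh1a7 did not pass without p66High parental replicate 1 or 2 or p66High aggressive replicate 3 (0.0531 to 0.0601).

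Camera called 15 lists, 7 higher and 8 lower. Of 21 glycolysis genes, 14 were higher (19 when adjusted over the list alone), with a median of 1.07 and an adjusted p of 7.8e-10, against an adjusted p = 0.653 with an estimated correlation. Gapdh rose by 2.14, Pgk1 by 1.52, Pfkp by 1.22 and Gpi1 by 1.20. Of 20 hypoxia genes, 13 were higher (18 when adjusted over the list alone), with a median of 1.66 and an adjusted p of 3.39e-08 (adjusted p = 0.827 with an estimated correlation). Car9 rose by 2.98, Ak4 and the oxygen sensor gene Egln1 each by 1.76, and Car12 by 0.93. The summed level of the hypoxia list was 1895, 3073 and 5770 CPM in the 3 p66High aggressive tumours. ErbB2 and Shc signalling genes had 5 of 22 higher and 1 lower (5 and 1 when adjusted over the list alone; median 0.24, adjusted p = 0.0171, adjusted p = 0.827 with an estimated correlation). The feedback inhibitor gene Spry4 (1.79), the Shc family gene Shc4 (1.37) and Etv5 (0.78) rose, and Dusp5 fell by 0.70.

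Luminal and milk genes had 6 of 22 lower (8 when adjusted over the list alone), with a median of -0.91 and an adjusted p of 0.00261 (adjusted p = 0.653 with an estimated correlation), including Csn2, Wap (-3.91), Csn1s1 (-2.99) and Cd14 (-1.02). Fatty acid synthesis genes had 5 of 15 lower (7 lower and 2 higher when adjusted over the list alone), with a median of -0.31 and an adjusted p of 0.00949 (adjusted p = 0.653 with an estimated correlation). The regulators Thrsp (-1.91) and Srebf1 (-1.10) and the enzymes Acaca (-0.77) and Scd1 (-2.70, 183 CPM against 1190 CPM) were lower. Adipocyte markers had 3 of 15 lower (3 when adjusted over the list alone), with a median of -2.49 and an adjusted p of 3.25e-06 (adjusted p = 0.827 with an estimated correlation), namely Lpl (-2.27), Retn and Cidea (-1.74). Their summed level was 234, 102 and 54.4 CPM against 593, 548 and 253 CPM in p66High parental tumours.

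Endothelial markers were lower as a list (median -0.67, adjusted p = 2.7e-05, adjusted p = 0.827 with an estimated correlation), with Egfl7 (-1.20) as the 1 of 18 members past the test (3 when adjusted over the list alone). Histone genes had 3 of 19 higher and 1 lower (14 and 1 when adjusted over the list alone; median 0.58, adjusted p = 6.61e-06, adjusted p = 0.827 with an estimated correlation). The linker histone genes H1f0 (0.74), Hist1h1e (0.88) and Hist1h1c (0.66) rose and Hist1h1a (-2.51) fell. The cell cycle list was called higher (median 0.41, adjusted p = 2.42e-05, adjusted p = 0.827 with an estimated correlation) with no member past the edgeR threshold over all genes or when adjusted over the list alone and 8 of 30 with an unadjusted p under 0.05, and Mki67 had a log2 change of 0.42 (adjusted p = 0.315). Mitochondrial genome genes were called higher (median 0.46, adjusted p = 0.00173, adjusted p = 0.827 with an estimated correlation), with no member past the edgeR threshold, 7 of 13 with an unadjusted p under 0.05 and 6 when adjusted over the list alone. Neutrophil markers (median -0.54, adjusted p = 0.0162, adjusted p = 0.653 with an estimated correlation) had S100a8 (-3.45) and Il1b (-1.76) as the 2 of 11 past the test (2 when adjusted over the list alone). Macrophage (median -0.36, adjusted p = 0.0162), fibroblast (-0.68, adjusted p = 0.00239) and type I interferon lists (-0.81, adjusted p = 0.000275) were called lower and the cholesterol synthesis list higher (0.23, adjusted p = 0.0144), each with an adjusted p = 0.827 with an estimated correlation. Their members past the test were Mertk (-0.89) among 2 of 20, Gsn (-1.43) as 1 of 18, no type I interferon gene in edgeR with 4 of 28 at an unadjusted p under 0.05, and Stard4 (0.55) as 1 of 23 (2, 1, 0 and 0 when adjusted over the list alone). The p53 list was not called (median -0.03).

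The count was 615, 457 and 592 without p66High parental replicate 1, 2 and 3, and 756, 661 and 568 without p66High aggressive replicate 1, 2 and 3, was 2261 with DESeq2, and was 305 when tumours whose titles share a number were summed. Without p66High aggressive replicate 3 the lists of type I interferon (adjusted p = 0.208), fibroblasts (0.127), macrophages (0.276), neutrophils (0.0665) and cholesterol synthesis (0.0715) were not called, nor were macrophages without p66High parental replicate 2 (0.0743) or cholesterol synthesis without p66High aggressive replicate 1 (0.104). In that fit without p66High aggressive replicate 3, medians were 0.14 for ErbB2 and Shc signalling, 0.93 for hypoxia, which was still called, -0.57 for luminal genes, -0.42 for type I interferon, -0.40 for fibroblasts and -0.06 for macrophages. The adipocyte median was -4.57 without p66High aggressive replicate 1, those of neutrophils and cholesterol synthesis were -1.005 and 0.38 without p66High aggressive replicate 2, and that of macrophages was -0.23 without p66High parental replicate 1. Of the list members named, Pfkp, Pgk1, Gpi1, Ak4, Egln1, Car12, Dusp5, Csn1s1, Cd14, Acaca, Scd1, Lpl, Cidea, Egfl7, Hist1h1e, Il1b, Mertk, Gsn and Stard4 did not pass in some of the 6 fits without 1 tumour (adjusted p up to 0.176).

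The fourth comparison addressed the difference between aggressive tumours with and without p66ShcA overexpression. Tumours of p66High aggressive cells expressed much less of the interferon, antigen presentation and immune cell genes than p66Low aggressive tumours, and more p53 target genes. B2m was at 171 CPM against 1489 CPM, and the antiviral gene Oas3 at 0.750 CPM against 19.4 CPM. Cdkn1a was at 18.5 ± 7.18 CPM against 4.02 ± 1.20 CPM, and Phlda3 at 46.7 CPM against 7.26 CPM. Genes of chromosome 1 were again higher in p66High tumours. Replicates 1 and 2 of the p66Low aggressive group held the lymph node genes.

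A total of 4077 of 19370 genes passed, 1728 higher (42.4%, or 32.7% with scaling by library size alone) and 2349 lower, and 1976 of them changed at least 2-fold. Groups did not overlap for 3927 called genes and for 38.2% of genes tested, where chance gives 10%. Sox14 was at least 327-fold higher, followed by Brinp3 (9.12, 103 ± 22.9 CPM against 0.188 CPM, adjusted p = 4.28e-06), Bspry (5.94), Ppp1r36 (5.66), the GABA receptor gene Gabrr1 (5.19), the transcription factor gene Onecut2 (4.97), Fbxo41 (4.77) and Col26a1 (4.53). Genes of B cells and lymph node stroma were among the lowest: Cr2 was at least 775-fold lower, the chemokine gene Ccl19 at least 167-fold and Faim3 at least 106-fold, and Glycam1 (-10.57) and Ms4a1 (-8.46) were also lower. Outside these cell types, Tlx3 was at least 109-fold lower (no count against 3.79 ± 0.302 CPM) and Dcaf12l2 at least 59.3-fold lower. The bounds of Cr2, Ccl19 and Faim3 were 236, 55.6 and 25.6 without p66Low aggressive replicate 2, and 1420 (Cr2), 305 and 194 without replicate 3. These 3 genes did not pass without any 1 of the 6 tumours except p66Low aggressive replicate 3 (adjusted p = 0.0650 to 0.124). Nor did Glycam1 and Ms4a1 without any 1 p66High aggressive tumour (0.0716 to 0.0813) or Ms4a1 without p66Low aggressive replicate 2 (0.0556).

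Camera called 23 lists, 7 higher and 16 lower. All 28 type I interferon genes were lower (28 when adjusted over the list alone), with a median of -3.25, an adjusted p of 6.94e-15 and an adjusted p = 0.602 with an estimated correlation. Oas3 (-4.67), Oas2 (-3.99), Mx1 (-3.61) and Ifit2 (-3.18) had the smallest p. Of 27 interferon gamma and antigen presentation genes, 25 were lower (27 when adjusted over the list alone; median -2.75, adjusted p = 7.15e-15, adjusted p = 0.602 with an estimated correlation), including Irf1 (-1.72), Ciita (-2.80) and B2m (-3.12). T cell markers had 18 of 20 lower (20 when adjusted over the list alone; median -4.22, adjusted p = 9.38e-09, adjusted p = 0.605 with an estimated correlation), with Cd4 at -3.90 and Cd8a at -4.09. NK and cytotoxic markers had 9 of 12 lower (12 when adjusted over the list alone; median -2.61, adjusted p = 2.44e-06, adjusted p = 0.602 with an estimated correlation), with Gzma at -2.65 and Klrk1 at -3.23. Dendritic cell markers had 14 of 17 lower (15 when adjusted over the list alone; median -2.80, adjusted p = 1.2e-07, adjusted p = 0.602 with an estimated correlation).

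Neutrophil markers had 8 of 11 lower (9 when adjusted over the list alone; median -2.29, adjusted p = 6.32e-05, adjusted p = 0.148 with an estimated correlation), among them Mmp9 (-2.34), Mmp8 (-2.29) and Il1b (-2.46). NF-kB and inflammatory genes had 12 of 22 lower and 1 higher (13 and 1 when adjusted over the list alone; median -0.75, adjusted p = 1e-05, adjusted p = 0.148 with an estimated correlation), including Birc3 (-1.24), Relb (-1.26) and Nfkbia (-0.72). Macrophage markers had 12 of 20 lower and 1 higher (13 and 1 when adjusted over the list alone; median -0.87, adjusted p = 0.00013, adjusted p = 0.605 with an estimated correlation). B and plasma cell markers had 12 of 16 lower (14 when adjusted over the list alone; median -6.66, adjusted p = 0.000316) and lymph node stroma markers 5 of 10 (10 when adjusted over the list alone; median -9.36, or -7.10 at the bound, adjusted p = 0.000859), both with an adjusted p = 0.685 with an estimated correlation. Without the 3 libraries rich in lymph node genes 1075 genes passed. In that fit 27 type I interferon genes (median -3.77), 16 interferon gamma genes (-3.17) and 2 T cell markers (-2.29) were lower, and the B cell list was not called (median -1.32, adjusted p = 0.114).

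Of 20 p53 targets, 13 were higher and 1 lower (14 and 1 when adjusted over the list alone), with a median of 0.78 and an adjusted p of 1.98e-07 (adjusted p = 0.148 with an estimated correlation). Ccng1 (0.89, 169 ± 10.8 CPM against 91.3 ± 4.26 CPM, adjusted p = 7.88e-05), Phlda3 (2.70), Eda2r (2.58), Cdkn1a (2.18), Bax (0.83) and Mdm2 (0.57) rose. Without the libraries rich in lymph node genes the median was 0.79. Ribosomal protein genes had 16 of 26 higher (22 when adjusted over the list alone; median 0.45, adjusted p = 7.44e-08, adjusted p = 0.637 with an estimated correlation), including Rps19 (0.67) and Rpl7 (0.88), which lies on chromosome 1. Oxidative phosphorylation had 9 of 30 higher and 1 lower (11 and 1 when adjusted over the list alone; median 0.23, adjusted p = 0.000482, adjusted p = 0.799 with an estimated correlation), with Atp5a1 at 0.85 and the chromosome 1 genes Sdhc (0.77) and Ndufs1 (0.71). Chromosome 1 had 525 of 1133 tested genes past the test, 400 higher and 125 lower, against 19.4% of genes on chromosomes other than 1 and 15, and a median log2 change of 0.44.

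Luminal and milk genes had 7 of 22 lower and 1 higher (8 and 1 when adjusted over the list alone; median -0.90, adjusted p = 0.0167, adjusted p = 0.602 with an estimated correlation), with Wap at -4.38, Spdef at -2.23 and the prolactin receptor gene Prlr at 0.70. ErbB2 and Shc signalling genes had 4 of 22 higher (4 when adjusted over the list alone; median 0.35, adjusted p = 0.00749, adjusted p = 0.605 with an estimated correlation), among them Shc1, the phosphatase gene Dusp4 (1.49), Etv5 (0.61) and Spred1 (0.49). Histone genes had 5 of 19 higher (5 when adjusted over the list alone; median 0.37, adjusted p = 0.00105, adjusted p = 0.801 with an estimated correlation). Mesenchymal genes had 6 of 24 lower and 1 higher (6 and 1 when adjusted over the list alone; median -0.58, adjusted p = 0.0109, adjusted p = 0.685 with an estimated correlation), with Tgfbi at -1.46 and Twist1 at 0.95. Fibroblast markers had 5 of 18 lower (6 when adjusted over the list alone; median -0.74, adjusted p = 0.0108, adjusted p = 0.932 with an estimated correlation), including C3 (-3.33). Adipocyte markers were called lower (median -1.82, adjusted p = 0.00536, adjusted p = 0.805 with an estimated correlation) with Retn (-4.26, and -3.49 with an adjusted p of 0.112 without p66Low aggressive replicate 1) as the 1 of 15 members past the test (0 when adjusted over the list alone, 5 at an unadjusted p under 0.05). Of the remaining called lists, cell cycle genes had 2 of 30 higher (1 when adjusted over the list alone; median 0.27, adjusted p = 0.014, adjusted p = 0.973 with an estimated correlation), Cenpf (0.91) and Mcm6 (0.69), both on chromosome 1. Mitochondrial genome genes had 2 of 13 higher (2 when adjusted over the list alone; median 0.47, adjusted p = 0.0167, adjusted p = 0.709 with an estimated correlation), mt-Cytb and mt-Nd2 (0.66 each). Nutrient transporters had 3 of 16 lower and 1 higher (3 and 1 when adjusted over the list alone; median -0.39, adjusted p = 0.0444, adjusted p = 0.605 with an estimated correlation), with the amino acid transporter genes Slc38a1 at -2.84 and Slc7a5 at 0.84. Skeletal muscle markers had Ttn, which encodes titin, as 1 of 10 lower (-3.74; 1 when adjusted over the list alone; median -1.22, adjusted p = 0.0446, adjusted p = 0.528 with an estimated correlation). Glycolysis (median 0.23) and hypoxia (0.34) lists were not called.

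The count was 2437 without p66Low aggressive replicate 2, and without the libraries rich in lymph node genes the medians of the adipocyte and fibroblast lists turned to 0.85 and 0.33. List calls that ended without 1 tumour were those of adipocytes (adjusted p = 0.0875), fibroblasts (0.0601) and mesenchymal genes (0.0516) without p66Low aggressive replicate 1. Calls also ended of fibroblasts (0.173) and mesenchymal genes (0.0654) without replicate 2 of that group, of fibroblasts (0.257), adipocytes (0.118) and mitochondrial genome genes (0.0519) without p66High aggressive replicate 3, and of mitochondrial genome genes without p66Low aggressive replicate 2 (0.0671). So did those of cell cycle genes without p66Low aggressive replicate 3 (0.274) or p66High aggressive replicate 1 (0.0585), of transporters without any 1 of the 6 tumours except p66Low aggressive replicate 3 (0.0550 to 0.0925), and of skeletal muscle without any 1 of the 6 (0.0504 to 0.0927). Medians were 0.22 for ErbB2 and Shc signalling and 0.47 for cell cycle genes without p66Low aggressive replicate 1, 0.13 for cell cycle genes and -1.16 for fibroblasts without p66Low aggressive replicate 3, -0.28 for mesenchymal genes and -0.33 for fibroblasts without p66Low aggressive replicate 2, and -4.10 for adipocytes without p66High aggressive replicate 1. Of the list members named, Mmp8, Cenpf, Mcm6, mt-Cytb, mt-Nd2, Slc7a5 and Ttn did not pass in some of the 6 fits without 1 tumour (adjusted p up to 0.138).

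**Figure D3:**
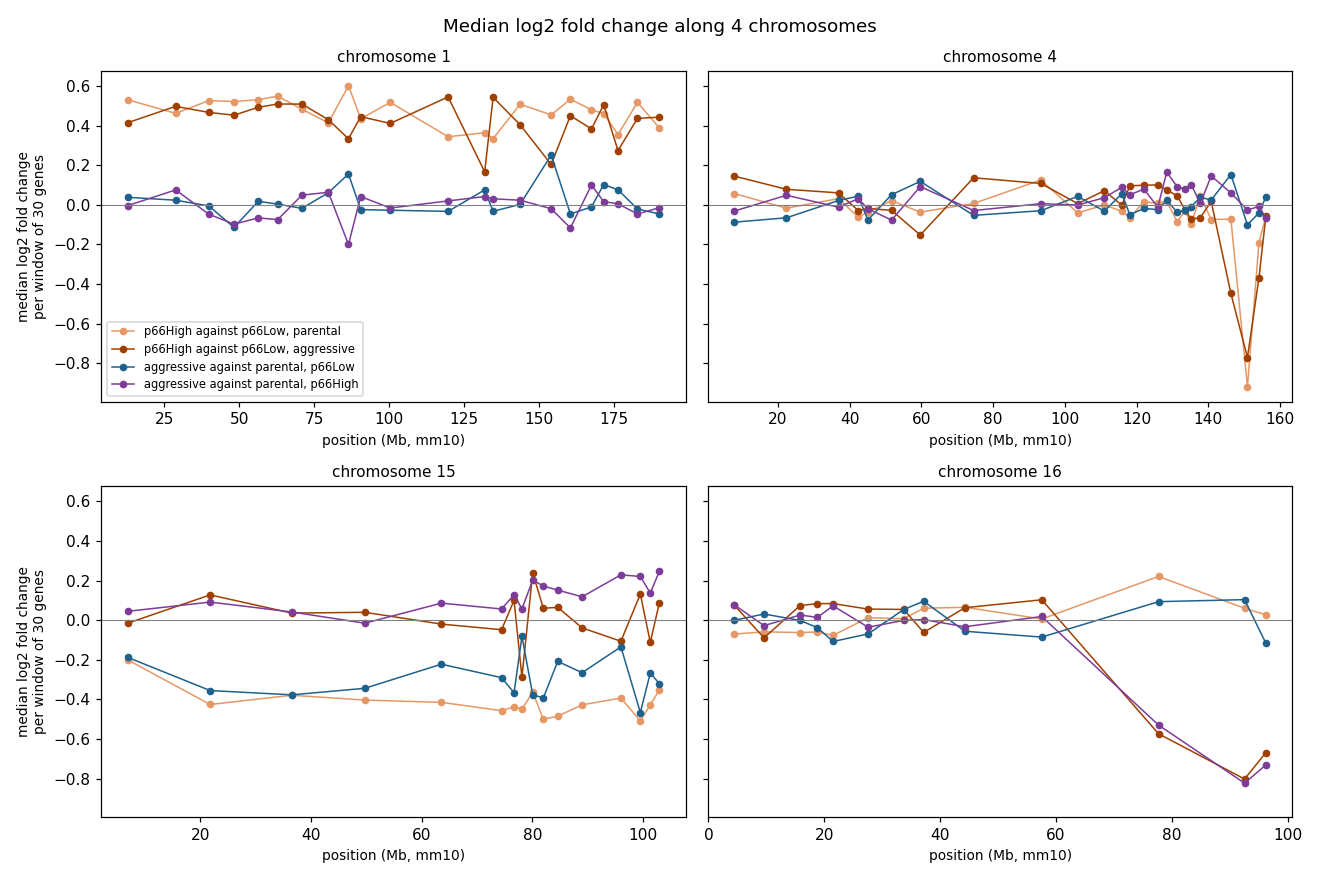
Each point is the median log2 fold change of a window of 30 neighbouring expressed genes (vertical axis) by position in Mb of mm10 (horizontal axis) on 4 chromosomes, with 1 line per comparison. On chromosome 1 the windows of p66High against p66Low lay between 0.33 and 0.60 in parental tumours and between 0.17 and 0.55 in aggressive tumours.

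The interaction compared the change with selection between both cell lines. It passed for 2395 genes (12.4%) and 28 lists, with 847 genes showing a more positive and 1548 a more negative change in p66High cells. With scaling by library size alone 23.3% of the called genes were more positive, against 35.4% in the main analysis. Of the p53 targets, 15 fell with selection of p66Low cells while the list was not called in p66High cells, and the difference itself passed for 12 of 20 targets in the positive direction and 1 in the negative (16 and 1 when adjusted over the list alone; median 0.84, adjusted p = 1.41e-08, adjusted p = 0.088 with an estimated correlation), with Cdkn1a at 3.88, Eda2r at 2.77, Bax at 1.15 and Ccng1 at 0.86. Interferon gamma genes had 21 of 27 more negative (26 when adjusted over the list alone; median -3.29, adjusted p = 1.21e-14, adjusted p = 0.557 with an estimated correlation). Type I interferon genes had 19 of 28 more negative (28 when adjusted over the list alone; median -3.11, adjusted p = 2.1e-12, adjusted p = 0.568 with an estimated correlation). Glycolysis genes had 8 of 21 more positive and 1 more negative (17 and 2 when adjusted over the list alone; median 1.19, adjusted p = 1.09e-05, adjusted p = 0.568 with an estimated correlation), with Pfkp at 1.77, Ldha at 1.31 and Aldoc at 1.10. Hypoxia genes had 4 of 20 more positive (16 more positive and 1 more negative when adjusted over the list alone; median 1.53, or 0.98 without p66High aggressive replicate 3, adjusted p = 0.000126, adjusted p = 0.603 with an estimated correlation), including Car9 (2.84) and Mxi1 (1.63). The count of 2395 was 1179 without p66Low parental replicate 3, 1442 without p66High parental replicate 3, 1182 without p66Low aggressive replicate 2, 1179 when tumours whose titles share a number were summed and 335 without the 3 libraries rich in lymph node genes. None of the 28 lists was called with an estimated correlation, and fry called 13.

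Some genes changed alike in both selections. Of genes past the test in both, 137 were higher in each (57.9 by chance) and 116 lower in each (38.4 by chance), while 47 and 41 went in opposite directions (52.5 and 42.4 by chance). Chst9 (4.35 in p66Low, 3.55 in p66High), Zfp641 (3.08, 3.73) and the neutrophil chemokine gene Cxcl5 (2.94, 3.26) rose in both. The quinone reductase gene Nqo1 (-3.36, -3.59), the keratin gene Krt15 (-3.41, -3.46), Clic3 (-5.69, -3.20) and Pitpnm3 (-2.40, -2.62) fell in both, with Pitpnm3 at -1.41 in p66Low without p66Low parental replicate 2. Krt15 and Pitpnm3 did not pass in p66High in 4 of the 6 fits without 1 tumour (adjusted p = 0.0519 to 0.0816), nor in p66Low without p66Low aggressive replicate 2 (Krt15, 0.0525) or 1 (Pitpnm3, 0.0518). Sftpd (3.65, -4.15) and Reep1 (3.05, -3.50) rose in p66Low and fell in p66High, and Dpysl5 (-3.39, 2.58), Rspo3 (-1.82, 2.73) and Asic1 (-1.63, 2.20) did the reverse. Over all genes tested, which are not independent replicates, Pearson's correlation of the log2 changes was -0.26 (jackknife SE 0.34), Spearman's was -0.10, and Pearson's was 0.00 without p66High parental replicate 3 and 0.18 without the 3 libraries rich in lymph node genes. Averaged over both cell lines, 2094 genes differed between aggressive and parental tumours, 1058 of them higher (50.5%, or 64.1% with scaling by library size alone), and the count was 1382 without p66High aggressive replicate 2 and 1126 when tumours whose titles share a number were summed.

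The p66High against p66Low changes of both selection states were likewise compared. A total of 391 genes were higher in both (68.7 by chance) and 205 lower in both (96.4 by chance), while 52 were higher in parental and lower in aggressive tumours (93.4 by chance) and 59 the reverse (70.9 by chance). Brinp3, Sox14, Bspry, Ppp1r36 and Onecut2 were higher in both. Tlx3, Zfp612 (-5.94, -6.89), Ranbp17 (-4.53, -5.52), Zfp385b (-6.79, -4.39) and Erbb4 (-4.38, -4.75) were lower in both. Cdkn1a (-1.70, 2.18), Col10a1 (-1.88, 3.21) and Fetub (-2.11, 2.69) turned from lower to higher, and the lymphocyte genes Xcl1 (2.31, -2.89), Cd7 (2.23, -3.55) and Gzma (2.14, -2.65) from higher to lower. The parental changes of Fetub, Xcl1 and Cd7 did not pass in 4 and that of Gzma in 5 of the 6 fits without 1 tumour (adjusted p = 0.0692 to 0.149). Pearson's correlation was -0.25 (jackknife SE 0.31), -0.00 without p66High parental replicate 3 and 0.16 without the 3 lymph node libraries. Averaged over selection, 3030 genes differed by p66 level, 1557 higher in p66High.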

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

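Of the tests weighed here, the second list of p53 targets, the correction for GC content, length and expression level and the counts over other splits of the samples were set before their results were seen, and the tests of lymph node tissue, tumour cell content and chromosome windows were chosen after the result was seen.

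The change with selection differed between p66High and p66Low cells, by the interaction term in edgeR, for 2395 genes and by camera for 28 lists, none of which was called with an estimated correlation, while fry called 13. The highest interaction log2 values were of Gipr (6.85), Gabrr1 (6.59), Sox14 (6.02), Dpysl5 (5.97) and Col10a1 (5.10). Among the lowest were the B cell genes Fcer2a (-19.96) and Cr2 (-18.88) and the lymph node chemokine genes Ccl19 (-16.53) and Ccl21a (-16.37). These 4 and Sox14 each have a group with no count, so their fitted values depend on the prior count and set no bound. Gipr was at 4.63 without p66High aggressive replicate 3, below Gabrr1 (6.45) in that fit, and no longer passed without the 3 libraries rich in lymph node genes (5.40), and Sox14 did not pass in 5 of the 12 fits that left out 1 tumour, which were those without p66Low parental replicate 1 (5.74) or 2 (5.46), p66High parental replicate 1 (6.02), p66Low aggressive replicate 2 (5.94) or p66High aggressive replicate 3 (6.04).

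Among the lists, the interaction median was positive for glycolysis (1.19) and p53 targets (0.84, adjusted p = 0.568 and 0.088 with an estimated correlation). It was negative for type I interferon response (-3.11), interferon gamma response and antigen presentation (-3.29), with an adjusted p = 0.568 and 0.557 with an estimated correlation, and for NF-kB and inflammatory cytokines (-1.09, adjusted p = 8.39e-08, adjusted p = 0.088 with an estimated correlation). Luminal and milk genes had a median of -1.68 (adjusted p = 0.0115, or 0.0801 without the 3 libraries rich in lymph node genes, and adjusted p = 0.557 with an estimated correlation). Immune cell lists were negative as well, with medians of -6.88 for T cells, -4.79 for NK cells, -3.49 for dendritic cells, -4.50 for mast cells, -2.39 for neutrophils and -1.13 for macrophages. With an estimated correlation the adjusted p was 0.557 for the first 3 of these, 0.562 for mast cells and macrophages and 0.187 for neutrophils. Without the 3 libraries rich in lymph node genes these 6 medians were -2.72, -3.76, -2.17, -0.40, -1.71 and -1.02, and the mast cell list was no longer called (adjusted p = 0.0924). The mast cell median was -9.15 without p66High aggressive replicate 1.

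Of 100 splits that exchanged p66 labels within parental and within aggressive tumours, 2 gave as many genes as the interaction, the real split with 2395 and a split with 3030 that exchanged every label of one selection group and so tests the effect of p66 averaged over selection. The highest other gave 1001 genes, but mixed p66 labels cannot separate an interaction from a p66 effect. For p66 averaged over selection, 1 of 100 splits, the real one with 3030 genes, gave as many, and the highest other gave 2395 by the same exchange. For selection averaged over p66, 1 of 100 gave as many, with 2094 genes in the real split and 1160 in the highest other. For both, the share of the drawn splits with as many genes was under 0.05. For comparisons of 3 against 3 tumours the 10 splits are too few for a share under 0.05: 1 split, the real one, gave as many genes in each, with 1565, 3221, 1150 and 4077 genes against 0, 2, 0 and 0 in the highest other split. All these splits treat tumours as exchangeable, which would not hold if the tumours that share a title number came from 1 mouse.

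The first pattern weighed is the higher level of lymphoid genes in p66Low aggressive tumours. Lymph node tissue carried with the fat pad may account for the B cell and lymph node stroma genes, since these appeared in the same 3 libraries, 1 of them p66High parental, in nearly 1 ratio (summed stroma CPM over summed B cell CPM of 1.63, 1.29 and 1.37, both without Cr2 and Fcer2a, which are in both lists, and the latter without plasma cell and immunoglobulin genes, coefficient of variation 0.124). It cannot account for p66Low aggressive replicate 3, which had few B cell genes but T cell genes at 5.18 times the highest p66Low parental tumour and interferon genes higher by a median of 3.14 on the log2 scale. T cells within the tumour and a tumour response to interferon stay open for that library, and whether either belongs to the group rests on 1 tumour without lymph node genes.

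The second pattern is the lower level of p53 targets in p66Low aggressive tumours. A lower share of tumour cells would lower epithelial genes by about as much, and their median was 0.0104 against -0.90 (exact two-sided Wilcoxon test, p = 0.000115, over genes, which are not independent replicates). A second list of 25 p53 targets that shares no gene with the first had a median of -0.70, with 12 lower and 1 higher, which is consistent with lower p53 activity in these tumours as a hypothesis. Protein, mutation and copy number of Trp53 were not measured here.

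The third pattern is the higher level of chromosome 1 genes in p66High tumours. Extra copies of chromosome 1 in the p66High cells may account for it: in the comparison with the lower share, 95.5% of 22 windows of 30 genes had a median above 0.2, against 3 of 359 windows elsewhere, and the median log2 CPM relative to the mean of the 12 tumours lay between 0.21 and 0.23 in all 6 p66High tumours and between -0.27 and -0.17 in all 6 p66Low tumours. A correction for GC content, length and expression level left a median of 0.469, the lower value of both comparisons, which argues against these as the cause. Each p66 level is 1 cell line here, so a gain that came with the line and an effect of p66ShcA on these genes are both open, and neither was tested.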

How the results depend on the processing

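The fits without the 3 libraries rich in lymph node genes, with a lymph node covariate and without chromosomes 1 and 15 were chosen after the result was seen, and the other alternatives were planned. No paired analysis was possible because replicate numbers only follow the order of deposit and pair no tumours across groups. Scaling by DESeq2 size factors, upper quartiles or library size alone, limma-voom, a robust fit and both other filters on low counts moved no count of genes by over 1.5 times. Where no cause is named for a change, the cause was not tested. Depth limits low genes. In simulated data 17.9%, 20.9% and 14.9% of genes changed 1.5-fold were recovered in p66Low selection, p66High selection and p66High against p66Low aggressive tumours. Of genes changed 4-fold, 83.3%, 95.5% and 90.9% were recovered.

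In the order p66High against p66Low parental, p66Low selection, p66High selection, p66High against p66Low aggressive, interaction, selection averaged and p66 averaged, leaving out 1 tumour gave 871 to 1926, 1545 to 3505, 457 to 756, 2437 to 4502, 1179 to 3278, 1382 to 2047 and 2266 to 3183 genes. These fits hold fewer samples. Called lists ranged over 10 to 16, 15 to 25, 13 to 21, 18 to 25 and 24 to 30 in the first 5. The correlation of changes ranged from -0.39 to 0.00 between cell lines and from -0.34 to -0.00 between selection states, and Shc1 from 1.83 to 1.98 in parental and from 1.86 to 2.97 in aggressive tumours.

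Without the 3 libraries rich in lymph node genes the counts were 838, 705, 586, 1075, 335, 969 and 1486 in the same order, with 1 tumour left in the p66Low aggressive group, which is assumed to vary like the others. The correlations turned to 0.18 between cell lines and 0.16 between selection states, and Shc1 was 2.60 in aggressive tumours (adjusted p = 0.0602). The lymph node covariate gave 1227 genes for p66Low selection, 1646 for p66High against p66Low aggressive and 504 for the interaction. Reversed were Glycam1 for p66Low selection without those libraries (-1.33) and with the covariate (-2.04), and, with the covariate, Glycam1 in the interaction (0.45) and Ms4a1 (0.0300) and Enpp2 (0.0295) in p66High against p66Low aggressive. A fold of at least 2, a stricter criterion, left 614, 1723, 642, 1976, 657 and 780 genes for all but the interaction. The DESeq2 Wald test gave 2549 for p66High against p66Low parental, 2261 for p66High selection and 3293 for selection averaged. Summing tumours whose titles share a number, which leaves fewer samples, gave 908 genes for p66High against p66Low parental, 305 genes and 23 lists for p66High selection, 1179 for the interaction and 1126 for selection averaged. Only the 6 tumours compared gave 2126 for p66Low selection, and leaving out chromosomes 1 and 15 gave 846 for p66High against p66Low parental. An estimated correlation left 0, 2, 0, 0 and 0 lists, with 0, 5, 3, 4 and 3 at an unadjusted p under 0.05, and fry called 0, 12, 4, 15 and 13.

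The naming rule took 238 genes in 416 comparisons, called or not. Of these, 270 kept their result whichever tumour was left out, and all 416 did with DESeq2. Those that kept direction but no longer passed numbered 86 with limma-voom, 104 with title numbers summed and 188 without lymph node libraries. There were 147 with the covariate, 26 with library size only, 26 with only 6 tumours and 12 with DESeq2 size factors. They were 9 with no filter, 8 with upper-quartile factors and 5 with the robust fit.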

Other observations

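The integrated stress response and NRF2 lists, the fits without 1 tumour and the genes Nqo1, Sesn2, Vldlr and Ddit4 follow the planned lists, alternatives and naming rule. All other values here were chosen after the result was seen, and none is a test of an explanation.

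Cdkn2a, whose products include the p53 activator Arf, rose with selection in both cell lines. It was at 63.3 ± 13.3 CPM against 14.0 ± 3.36 CPM in p66Low (log2 2.18, edgeR adjusted p = 0.000731) and at 88.2 ± 10.4 CPM against 26.6 ± 9.27 CPM in p66High tumours (1.73, adjusted p = 0.00387; SD, n = 3). Its neighbour Cdkn2b had log2 changes of 0.54 (adjusted p = 0.14) and 0.49 (adjusted p = 0.23). Nqo1, a target of the antioxidant regulator NRF2, fell with selection in both lines, to 2.14, 2.14 and 2.48 CPM from a mean of 23.3 CPM in p66Low and to a mean of 1.76 CPM from 21.1 CPM in p66High tumours, while the list of glutathione and NRF2 targets was not called in either (medians -0.11 and -0.05 over 23 genes). Integrated stress response genes were called in the interaction, with 5 of 19 more positive and 1 more negative (5 and 1 when adjusted over the list alone; median 0.49, adjusted p = 0.0301, adjusted p = 0.613 with an estimated correlation), among them Sesn2 (1.17), Vldlr (1.03) and Ddit4 (2.14). That call ended without p66Low aggressive replicate 1 (adjusted p = 0.0693), p66High aggressive replicate 3 (0.0829) or p66Low parental replicate 1 (0.0810), and the median was 0.31 and 0.26 in the first 2 of these fits and 0.32 without p66High aggressive replicate 2.

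Parts of other chromosomes moved as blocks. On mm10 chromosome 4, from 149467572 to 152334071, 24 of 30 expressed genes were lower and 1 higher in p66High tumours, both parental (median log2 -0.92) and aggressive (-0.77). On chromosome 16, from 64851996 to 98031801, 50 of 80 genes were lower and 3 higher in p66High aggressive against p66High parental tumours (median -0.75), and 57 lower and 7 higher against p66Low aggressive tumours (-0.74). On chromosome 15 all 16 windows of 30 genes lay below -0.2 in p66High against p66Low parental tumours, as did 13 of 16 in p66Low aggressive against p66Low parental and 1 of 16 in p66High against p66Low aggressive tumours. The chromosome 15 median log2 CPM relative to the mean of the 12 tumours was 0.37, 0.06 and 0.29 in p66Low parental and lay between -0.18 and -0.12 in p66High parental, between -0.09 and -0.03 in p66Low aggressive and between -0.12 and 0.07 in p66High aggressive tumours.

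The non-coding X chromosome RNA gene Xist was at 265 and 515 CPM in p66Low parental replicates 1 and 3, at 1480 CPM in replicate 2 and between 877 and 1595 CPM in the other 9 tumours.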
